A study of Homo sapiens with 6 samples.

How the data were processed

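RNA sequencing had been done on KYSE30 cells, an established human cell line derived from an oesophageal squamous cell carcinoma. Per the labels' protocols, the cells were transfected with a control siRNA (si-NC) or with 1 of 2 siRNAs against RAB23 (si-RAB23-1 and si-RAB23-9) at 100 nM with a lipid reagent, and total RNA was extracted with Trizol at about 80% confluence. The 6 libraries fall into 3 groups of 2 by their titles, and the series design names si-NC as the reference of both RAB23 siRNAs. The labels call the libraries of a group biological replicates and do not say whether they came from separate cultures. The limma p-values of single genes therefore measure the spread between these libraries, which may be partly technical. Camera at its preset correlation and the permutation tests, both used below, compare genes with other genes. The exact binomial tests compare pooled reads. The p-values of these tests treat genes or reads, not libraries, as replicates. The sequences of the siRNAs, the time between transfection and harvest, the strandedness of the libraries and the read length are not given in the sources used here.

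The values are FPKM, fragments scaled to gene length and library size, in 1 column per library of the table the authors deposited. FastQC, Trimmomatic 0.36, STAR 2.5.1b, RSEM 1.2.29, edgeR 3.8.5 and the build hg19 are named per the submitters' processing notes, without the role of each. The start and end of all 58735 genes in the table equal those of GENCODE release 29 on GRCh38, so coordinates below are on GRCh38 as the table gives them. After multiplication by the gene length in the same table, 100% of the values were whole multiples of 1 step per library, within 0.01 of a read (largest deviation 0.000112). The values thus come from whole reads per gene, although RSEM, which the notes name, estimates reads that need not be whole. The recovered reads came to 24178125 and 19752125 for si-NC, 17211025 and 22789183 for si-RAB23-1, and 19179885 and 17959115 for si-RAB23-9. The denominator behind the FPKM was 0.963 to 0.990 times these totals.

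In 27 cases a spreadsheet had turned the gene symbol into a date, and all 27 were resolved by gene ID. Reads shared by near-identical or overlapping genes, and reads of antisense pairs, could have been assigned to either gene, and values of such genes are uncertain. Of 35196 genes above 0 in at least 1 library, 14352 with FPKM of at least 1 in at least 2 libraries were tested, 10959 of them protein coding. Of these, 974 had a mean under 10 recovered reads per library.

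The tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with values as deposited. A linear model with 1 mean per group was fitted to all 6 libraries, followed by eBayes with a mean-variance trend (3 residual degrees of freedom), for si-RAB23-1 minus si-NC, si-RAB23-9 minus si-NC and si-RAB23-9 minus si-RAB23-1. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. FPKM is a normalized value, so a model for counts was not the main test. A count model had been planned only for the case that the table held counts.

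A total of 36 gene lists were drawn up for this line and treatment. They covered the Hedgehog pathway, Rab GTPases, the RAB23 exchange factor with cilium trafficking, integrins and focal adhesion, epithelial junction and keratin, mesenchymal genes, squamous differentiation, TGF-beta targets, ERK feedback targets, YAP targets and Wnt targets. They also covered S phase, G2 and mitosis, p53 targets, apoptosis regulators, interferon response, NF-kappaB and inflammatory cytokines, the unfolded protein response and amino acid starvation (ATF4). Metabolic and other lists were cholesterol biosynthesis, hypoxia and glycolysis, nuclear oxidative phosphorylation genes, ribosome biogenesis and MYC targets, autophagy and lysosome, the RNA interference machinery, immediate early genes, heat shock and NRF2 targets. The rest were replication-dependent histones, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, housekeeping reference genes, and markers of fibroblasts, leukocytes, endothelium and simple columnar epithelium. The last 4 had fewer than 5 tested members and no set test. The other 32 were tested with limma's camera at a preset correlation of 0.01, adjusted over 64 tests for the 2 comparisons with si-NC and over 32 tests for the siRNAs against each other. Camera with an estimated correlation and fry were run beside it. Members were counted at an adjusted p over all genes and adjusted over the list alone.

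The genes named were RAB23, then the 10 higher and 10 lower genes called for both siRNAs in the same direction with the largest smaller fold change. For each siRNA the 5 higher and 5 lower called genes of largest fold change followed, if the siRNAs also differed for them. In each list up to 4 members of smallest p were named. All had a mean FPKM of at least 2 and both libraries of the siRNA on the same side of both si-NC libraries, which chance alone gives for 33.3% of genes with 2 against 2. Any other gene named below was chosen after its values were seen. The groups, tests, lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated.

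The shared si-NC libraries were dealt with by 100 simulations of unchanged groups with the fitted spread of each gene, and by the overlap that independent lists of the same lengths would give. The model was tested on simulated data for si-RAB23-1 against si-NC with 200 genes changed before the filter, which kept 14141 genes. It recovered 73 of the 97 kept genes changed 2-fold (75.3%) and 53 of the 98 changed 1.5-fold (54.1%), with 8 false calls, and none of the genes of the unchanged siRNA group was called. In a separate simulation of this kind 1 list was changed 1.3-fold and was found at an adjusted p of 3.23e-70 by camera, and 0 of the other lists were called. Simulated genes varied independently, with 1 spread between replicates for all (SD 0.0235 on the natural log scale). The simulation therefore does not test the preset correlation. In the real data the estimated correlation was 0.40 for G2 and mitosis and 0.35 for ribosome biogenesis.

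Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, the replicate number as a block, only the 2 groups compared in the model, eBayes without the trend or robust, a log2 fold change of at least 1, and each library left out. Most of the named gene results lost their call without at least 1 library, which is stated below for some genes only. After the data had been seen, limma's voom on the recovered reads, with library totals or median-of-ratios sizes, and a mean of at least 10 reads were added. So was a comparison of the siRNAs' fold changes with a different si-NC library as the control of each, with standard errors from leaving out each chromosome in turn.

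Annotated 3′ UTRs of GENCODE release 29 were also scanned for 7-mers related to the fold changes, an analysis added after the data had been seen. For each gene the coding transcript with the longest 3′ UTR was used, whether or not these cells express it. A gene said to carry a 7-mer carries it in that transcript. Each 7-mer with at least 30 carriers entered a linear model with UTR length, base composition and expression, over 9467 of 9574 eligible protein-coding genes (98.9%) with a UTR of at least 50 bases and a mean FPKM of at least 2. Shares of carriers that rose or fell are raw counts, without the adjustments of this model. A 7-mer planted in shuffled fold changes of si-RAB23-1 minus si-NC (146 carriers, log2 effect of -0.15) ranked 1 over those 9467 genes. The scan and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.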

Results

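The series asked which transcripts change in oesophageal squamous carcinoma cells when RAB23 is lowered by RNA interference. KYSE30 cells had received si-NC, si-RAB23-1 or si-RAB23-9, with 2 libraries each and between 17211025 and 24178125 recovered reads per library. Between 13576 and 13700 genes had an FPKM of at least 1 in a library. Spearman correlations were 0.983 to 0.985 between libraries of a group and 0.969 to 0.979 between groups. The first principal component (34.4% of the variance) placed the RAB23 siRNAs at its opposite ends, with si-NC between them. The next one (25.9%) set si-NC apart from both. Replicates differed by more than sampling noise in each group, with chi-square values per degree of freedom of 2.45 for si-NC, 3.76 for si-RAB23-1 and 1.81 for si-RAB23-9.

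RAB23 transcript fell with both siRNAs. RAB23 (ENSG00000112210, chromosome 6, 57186992 to 57222314) encodes a small GTPase of the Rab family known as a negative regulator of Hedgehog signalling. Its level was 3.30 ± 0.0483 FPKM with si-NC, 1.06 ± 0.0470 with si-RAB23-1 and 1.23 ± 0.0621 with si-RAB23-9 (SD, n = 2 each), that is 0.322 and 0.372 times the control. On the log2 scale it fell by 1.06 (SE 0.0815, limma adjusted p = 0.00314) and by 0.95 (limma adjusted p = 0.00392). The residual levels differed by 0.11 between the siRNAs, which did not pass the test (limma adjusted p = 0.383). The values rest on 384 and 321 reads with si-NC, 84 and 120 with si-RAB23-1, and 110 and 111 with si-RAB23-9. The log2(FPKM + 1) scale understates the fall of a gene at this level. Voom on the recovered reads, added after the data had been seen, gave -1.65 and -1.43.

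**Figure D1:**
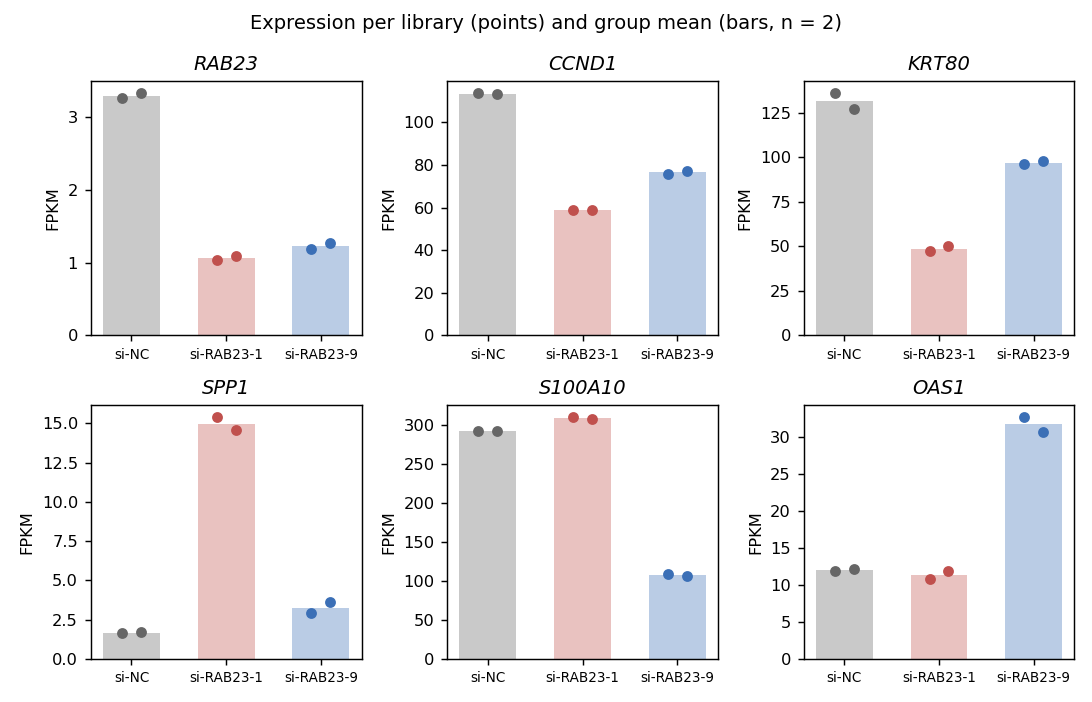
FPKM of RAB23, CCND1, KRT80, SPP1, S100A10 and OAS1 in each of the 6 libraries, with points for libraries and bars for group means (n = 2 per group), each panel with its own linear axis from 0. RAB23 fell from 3.30 to 1.06 and 1.23 FPKM. SPP1 reached 15.4 and 14.6 FPKM with si-RAB23-1, and S100A10 fell (107.8 FPKM) and OAS1 rose (31.7 FPKM) with si-RAB23-9.

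With si-RAB23-1, SPP1, TM4SF1, MARCKS, AREG and CTGF rose, and KRT80 and TP53INP1 fell, all by more than 2-fold on the log2 scale used. SPP1 (chromosome 4, 87975650 to 87983426), which encodes the secreted protein osteopontin, was at 1.62 and 1.72 FPKM with si-NC and at 15.4 and 14.6 with si-RAB23-1 (log2 fold change 2.58, limma adjusted p = 0.000975). TM4SF1, a surface protein gene, rose by 1.35 and MARCKS, which encodes an actin-binding kinase substrate, by 1.17. AREG, the gene of the EGF receptor ligand amphiregulin, and the matricellular protein gene CTGF both rose by 1.12. KRT80 (chromosome 12, 52168996 to 52192000), an epithelial keratin gene, fell from 131.7 ± 6.45 to 48.7 ± 1.88 FPKM (log2 fold change -1.42, limma adjusted p = 0.000975). TP53INP1, a target of p53, fell from 10.6 ± 0.372 to 3.72 ± 0.362 FPKM (limma adjusted p = 0.00184). HIST1H2BC (7.25 ± 1.02 to 2.63 ± 0.855 FPKM) and ALPP (log2 fold change -1.19) also fell, and both belong to families with near-identical copies. With si-RAB23-9 the changes of SPP1 (0.67), TM4SF1 (0.49), MARCKS (0.59), KRT80 (-0.43) and TP53INP1 (-0.47) also passed the test and were smaller. Only that of MARCKS held with any 1 library left out: TM4SF1 and TP53INP1 were lost without any si-NC or si-RAB23-9 library (limma adjusted p up to 0.0836 and 0.0846), SPP1 without either si-NC library (up to 0.0713) and KRT80 without either si-RAB23-9 library (up to 0.0552). The pseudogene AC233266.1 passed the test (-1.72) on 21 reads with si-NC and 3 with si-RAB23-1. The annotated 3′ UTRs of KRT80, TP53INP1 and HIST1H2BC contain the 7-mer GACATAT, and 30.9% of its 705 carriers fell with si-RAB23-1 against 7.86% of the other genes scanned. The TGF-beta target INHBA holds it too and was called higher with si-RAB23-1. The calls of HIST1H2BC, ALPP and AC233266.1 were lost without either si-NC library, with limma adjusted p between 0.0576 and 0.0994, and that of AC233266.1 also without si-RAB23-1 replicate 2 (0.0559).

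By limma, 1167 genes were higher and 1042 lower with si-RAB23-1 than with si-NC among 14352 tested, with a median absolute log2 fold change of 0.32 among those called. A log2 fold change of at least 1 was reached by 24 higher and 18 lower genes. The counts were 205 and 182 without si-NC replicate 1, 173 and 165 without si-NC replicate 2, 531 and 538 without si-RAB23-1 replicate 1, 641 and 610 without si-RAB23-9 replicate 1, and 642 and 611 without si-RAB23-9 replicate 2. Voom on the recovered reads with library totals called 1622 higher and 2178 lower.

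By camera at the preset correlation, the lists of ribosome biogenesis and immediate early genes shifted to higher with si-RAB23-1. Those of the cell cycle and p53 targets shifted to lower, although most S phase genes and p53 targets were not called singly. None of these lists was called with an estimated correlation. Of 36 ribosome biogenesis genes and MYC targets, 20 rose (31 adjusted over the list alone), with a median log2 fold change of 0.22. This list had a camera adjusted p = 1.21e-12 (adjusted p = 0.551 with an estimated correlation). The transcription factor gene MYC rose by 1.03, NOLC1, which encodes a nucleolar phosphoprotein, by 0.90, the polyamine synthesis gene ODC1 by 0.67 and RRP12 by 0.48. Of 18 immediate early genes, which respond to growth factors and stress, 10 rose (12 adjusted over the list alone), with a median of 0.26. Camera gave an adjusted p = 1.2e-06 here (adjusted p = 0.551 with an estimated correlation). CYR61 rose by 1.07, KLF6 by 0.97 and JUN by 0.53, and MYC belongs to this list as well.

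Of 45 genes of G2 and mitosis, 24 fell with si-RAB23-1 (29 adjusted over the list alone), with a median of -0.22. Their camera adjusted p was 6.93e-12 (adjusted p = 0.618 with an estimated correlation). CCNB1, the gene of cyclin B1, fell by 0.30, CDC20 by 0.28, the mitotic kinase gene PLK1 by 0.32 and UBE2C by 0.36. In the list of S phase and DNA replication, 6 of 41 fell (7 adjusted over the list alone), with a median of -0.12 and a camera adjusted p = 9.5e-05 (adjusted p = 0.551 with an estimated correlation). Among them were the replicative helicase genes MCM4 (-0.29), MCM2 (-0.25) and MCM5 (-0.24). With 1 library left out these ranged from -0.349 to -0.239, -0.301 to -0.197 and -0.269 to -0.202. Each of the MCM calls was lost without at least 1 library. Of 24 p53 targets 8 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.16 and a camera adjusted p = 0.000577 (adjusted p = 0.551 with an estimated correlation). The cell cycle inhibitor gene CDKN1A fell by 0.66 and MDM2, which encodes the ubiquitin ligase of p53, by 0.38, while PLK2 rose by 0.65. The cytosolic ribosomal protein list was also called as higher (camera adjusted p = 0.00298; adjusted p = 0.661 with an estimated correlation). Limma called 1 of its 70 members, RPL35 (0.11), and 0 when adjusted over the list alone. At an unadjusted p under 0.05 it gave 16 higher and 1 lower, and voom with median-of-ratios sizes called 8 and 1. This list's direction turned under quantile normalization (adjusted p = 0.884), and its call was lost without si-RAB23-1 replicate 1 (0.0862), with a mean FPKM of at least 5 (0.0587) and by voom with library totals (0.11).

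With si-RAB23-9, interferon-induced genes led the increases. BST2, the gene of the antiviral membrane protein tetherin, rose from 5.79 ± 0.553 to 22.9 ± 0.713 FPKM (log2 fold change 1.82, limma adjusted p = 0.00143). IFI6 rose by 1.74, IFITM1 by 1.70, and the oligoadenylate synthetase genes OAS2 and OAS1 by 1.38 and 1.33. S100A10 (chromosome 1, 151982915 to 151994390), which encodes the annexin A2 partner p11, fell from 293 ± 0.392 to 107.8 ± 2.21 FPKM (log2 fold change -1.43, limma adjusted p = 0.000103). NCEH1, a cholesteryl ester hydrolase gene, fell by 1.46 and the transporter family gene MFSD6 by 1.15. The annotated 3′ UTRs of S100A10, NCEH1 and MFSD6 contain the 7-mer AAGTTAA, of whose 1563 carriers 328 fell with si-RAB23-9, against 4.87% of the other genes scanned. Not all carriers fell: MARCKS, ID3, LIG1 and DROSHA each hold 1 copy and were called higher with si-RAB23-9. RF00019 (-1.13) rests on 13 reads with si-NC and 3 with si-RAB23-9, and the lincRNA gene AC005392.2 (-1.07) on 44 and 12. Both calls were lost without any 1 of the si-NC or si-RAB23-9 libraries (limma adjusted p = 0.0809 to 0.174 and 0.0701 to 0.119). IFITM1 lies within the coordinates of IFITM2, so reads could be assigned to either.

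By limma, 1085 genes were higher and 817 lower with si-RAB23-9 than with si-NC, with a median absolute log2 fold change of 0.33 among those called. A log2 fold change of at least 1 was reached by 24 and 19 of them. Without si-NC replicate 1 the counts were 186 and 127, without si-NC replicate 2 165 and 121, without si-RAB23-9 replicate 1 174 and 172, and without si-RAB23-9 replicate 2 143 and 115. Voom with median-of-ratios sizes called 1802 higher and 1605 lower.

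The interferon list had the largest median shift of the 32 lists tested with si-RAB23-9. Of its 39 tested members 29 rose (35 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.64 and a camera adjusted p = 7.51e-22 (adjusted p = 0.315 with an estimated correlation). IFI44 rose by 1.27, OAS3 by 1.15 and IFIT1 by 1.06. Of 15 NF-kappaB targets and inflammatory cytokines, 6 rose (10 adjusted over the list alone), with a median of 0.19 and a camera adjusted p = 0.000152 (adjusted p = 0.551 with an estimated correlation). The chemokine gene CXCL8 rose by 0.94, and TNFAIP3 and NFKBIA, which encode inhibitors of NF-kappaB, by 0.47 and 0.23. Of 41 S phase genes 15 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.18 and a camera adjusted p = 2.52e-06 (adjusted p = 0.551 with an estimated correlation). RFC2 rose by 0.43, GINS2 by 0.40 and MCM3 by 0.26. The calls of GINS2, MCM3 and NFKBIA were each lost without at least 1 library. Their changes then ranged from 0.334 to 0.457, 0.25 to 0.276 and 0.219 to 0.236. The S phase gene that fell was RRM2 (-0.62), the gene of a ribonucleotide reductase subunit, whose 3′ UTR holds 3 copies of AAGTTAA.

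Of 26 genes of the amino acid starvation response 11 rose and 2 fell with si-RAB23-9 (16 and 2 adjusted over the list alone). This list had a median of 0.19 and a camera adjusted p = 0.000578 (adjusted p = 0.551 with an estimated correlation). TRIB3 rose by 0.54, the serine synthesis gene PHGDH by 0.38, and the glutamine transporter gene SLC1A5 and AARS by 0.33 each. Of 23 YAP targets 10 fell and 1 rose (12 and 3 adjusted over the list alone), with a median of -0.22 and a camera adjusted p = 0.000114 (adjusted p = 0.551 with an estimated correlation). TGFB2 fell by 0.82, AJUBA, which carries AAGTTAA, by 0.63 and the ecto-nucleotidase gene NT5E by 0.62, while IGFBP3 rose by 0.51. Of 36 ribosome biogenesis genes 5 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.11 and a camera adjusted p = 0.000633 (adjusted p = 0.661 with an estimated correlation). NOLC1 rose by 0.76, MYC by 0.51 and NOP56 by 0.24, and the member that fell was DDX21 (-0.51), with 2 copies of AAGTTAA. The calls of MYC, NOP56 and DDX21 were each lost without at least 1 library, while that of NOLC1 held throughout.

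With larger camera p values, 3 further lists were called with si-RAB23-9. Of 18 immediate early genes 4 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.14 and a camera adjusted p = 0.0324 (adjusted p = 0.628 with an estimated correlation). JUN rose by 0.41 and IER2 by 0.30. Of 9 histone genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.27 and a camera adjusted p = 0.0438 (adjusted p = 0.628 with an estimated correlation). HIST1H2BK fell by 0.78, HIST2H2BE by 0.52 and HIST1H1C by 0.50, and HIST1H2BD rose by 0.48. Only HIST1H2BK among them kept its call with any 1 library left out. The mitochondrially encoded mRNAs were called as lower, with a median of -0.07 and a camera adjusted p = 0.0207 (adjusted p = 0.692 with an estimated correlation). Limma called 0 of these 13 genes, also when adjusted over the list alone, with 4 lower at an unadjusted p under 0.05 and 5 lower by voom with median-of-ratios sizes. The calls of these lists, in this order, were lost under quantile normalization (adjusted p = 0.0531, 0.0583 and 0.788) and without si-NC replicate 2 (0.191, 0.0626 and 0.0626). The immediate early and histone lists were also lost without si-RAB23-9 replicate 1 (0.0606 and 0.169), the histones with median-of-ratios scaling (0.053), the immediate early genes with a mean FPKM of at least 5 (0.158), and the mitochondrial list without a filter (0.385) and without si-RAB23-9 replicate 2 (0.116).

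Both siRNAs changed a common set of genes. TPM4 (chromosome 19, 16067021 to 16103005), a tropomyosin gene, was at 21.3 ± 1.24 FPKM with si-NC and at 2.34 and 2.12 times that level with si-RAB23-1 and si-RAB23-9 (log2 fold changes 1.19 and 1.05, limma adjusted p = 0.00184 and 0.00197). In the same order CXCL8 rose by 0.89 and 0.94, AREG by 1.12 and 0.76, NOLC1 by 0.90 and 0.76, OGFR by 0.73 and 1.02, and RTN2 by 0.86 and 1.00. MGP, the gene of matrix Gla protein, rose by 1.02 and 0.83, TCIM by 0.89 and 0.81, and the transcription factor gene SOX21 by 0.98 and 0.72. CCND1 (chromosome 11, 69641087 to 69654474), which encodes cyclin D1, fell from 113.6 ± 0.324 to 58.9 ± 0.183 and 76.5 ± 0.771 FPKM (log2 fold changes -0.94 and -0.56, limma adjusted p = 0.000975 and 0.00143). The annotated 3′ UTR of CCND1 carries none of GACATAT, AAGTTAA and TCGGAGA, and no other 7-mer was looked up in it. SEPTIN10 fell by 0.85 and 0.78, the clathrin adaptor gene AP1S3 by 0.80 and 0.66, and PADI1, a peptidylarginine deiminase gene, by 0.63 and 0.64. CYP4F3 fell by 0.59 and 0.76, ENPP4 by 0.57 and 0.75, RNF223 by 0.58 and 0.57, and CYSRT1 by 0.57 and 0.68. The lincRNA gene AC254633.1 (-0.56 and -0.79) also passed both tests. So did the small nuclear RNA pseudogene RNU6ATAC18P, on 28 reads with si-NC and 14 and 11 with the RAB23 siRNAs, and the antisense gene AC010542.5, on 16, 38 and 37 reads that cannot be told from its sense partner without strand. Among the genes that fell, SEPTIN10 and ENPP4 hold AAGTTAA in their 3′ UTR, as do TPM4, SOX21 and TCIM, which rose. TPM4 and NOLC1 hold the 7-mer TCGGAGA, whose 204 carriers were higher as a set with both siRNAs. With any 1 library left out, TPM4, CXCL8, AREG, NOLC1, OGFR, RTN2, CCND1, SEPTIN10, AP1S3 and PADI1 passed both tests, and each of the other genes lost at least 1 of its calls without a si-NC library.

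By limma, 420 genes were higher and 218 lower with both siRNAs, against 88.2 and 59.3 for independent lists. In 100 simulations of unchanged groups sharing the si-NC libraries the overlap was 0. That value leaves out real effects, and the one for independent lists leaves out the shared controls, so neither gives the overlap that shared controls add to real effects. A further 52 genes rose with si-RAB23-1 and fell with si-RAB23-9, and 45 did the reverse (66.4 and 78.8 for independent lists). Across genes, which are not independent replicates, the fold changes correlated with Pearson r = 0.395 and Spearman rho = 0.346. The simulations gave means of 0.503 and 0.456 from the shared controls alone. The covariance was 0.0243, against a simulated mean of 0.00982 and maximum of 0.0115. With a different si-NC library as the control of each siRNA, a comparison chosen after the data had been seen, the covariance was 0.00868 and 0.011 and Pearson r 0.113 and 0.148. The shared controls thus added more covariance (0.0144, from the difference of the si-NC libraries) than the simulations held. Part of the overlap may come from them, since the si-NC group cannot be split into parts of 2 libraries. The counts were 55 and 19 without si-NC replicate 1 and 57 and 19 without si-NC replicate 2, where the covariance was 0.0422 and 0.0353. They were 90 and 41 without si-RAB23-9 replicate 1, and 78 and 28 without si-RAB23-9 replicate 2.

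**Figure D2:**
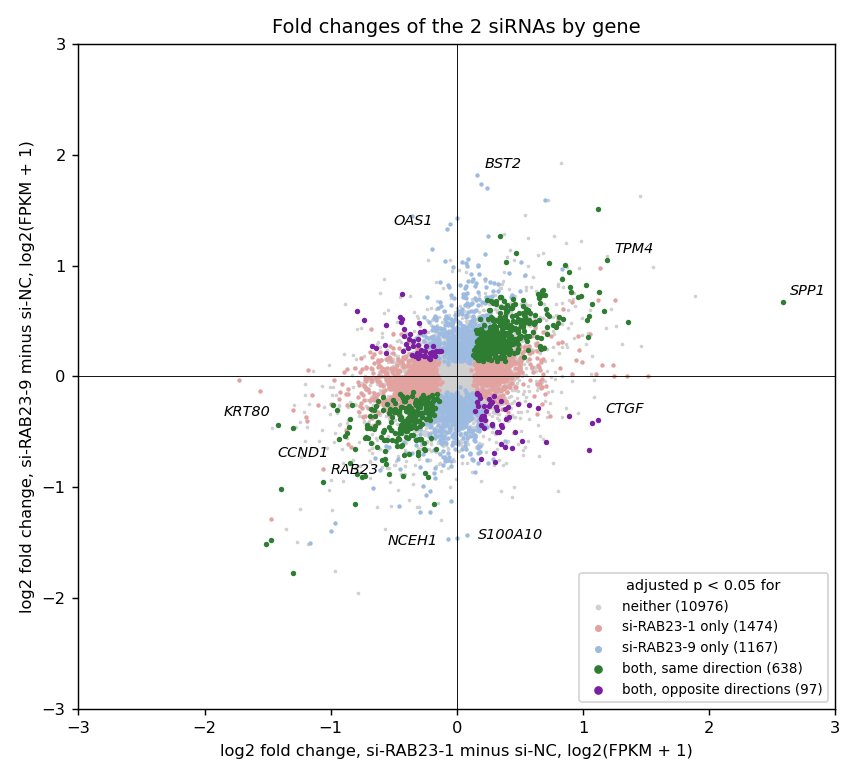
Log2 fold change of each of 14352 genes with si-RAB23-1 (horizontal) and si-RAB23-9 (vertical), both minus si-NC on log2(FPKM + 1), coloured by which siRNA passed a limma adjusted p of 0.05. Of the genes, 638 passed for both in the same direction, 97 for both in opposite directions, 1474 for si-RAB23-1 only and 1167 for si-RAB23-9 only. RAB23 and CCND1 lie in the lower left, and BST2 and S100A10 near the vertical axis.

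The siRNAs also differed from each other directly, with 1599 genes higher and 1420 lower with si-RAB23-9 than with si-RAB23-1 by limma. CTGF differed by -1.51 (limma adjusted p = 0.0013), having risen with si-RAB23-1 and fallen by 0.39 with si-RAB23-9, whose leading 7-mer its 3′ UTR holds. Its fall was lost without any 1 of the si-NC or si-RAB23-9 libraries (limma adjusted p = 0.0912 to 0.178). In the interferon list 32 of 39 members were higher with si-RAB23-9 (33 adjusted over the list alone), with a camera adjusted p = 6.75e-18 (adjusted p = 0.214 with an estimated correlation). S phase genes were higher in 26 of 41 cases and lower in 1 (30 and 1 adjusted over the list alone), with a camera adjusted p = 3.87e-11 (adjusted p = 0.239 with an estimated correlation). Genes of G2 and mitosis were higher in 27 of 45 cases (28 adjusted over the list alone), with a camera adjusted p = 6.2e-10 (adjusted p = 0.463 with an estimated correlation). YAP targets were lower in 13 of 23 cases (15 lower and 1 higher adjusted over the list alone), with a camera adjusted p = 2.77e-06 (adjusted p = 0.239 with an estimated correlation). The gene counts were 1032 and 891 without si-NC replicate 1, 1026 and 880 without si-NC replicate 2, 753 and 613 without si-RAB23-1 replicate 1, 438 and 414 without si-RAB23-9 replicate 1, and 375 and 330 without si-RAB23-9 replicate 2.

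**Figure D3:**
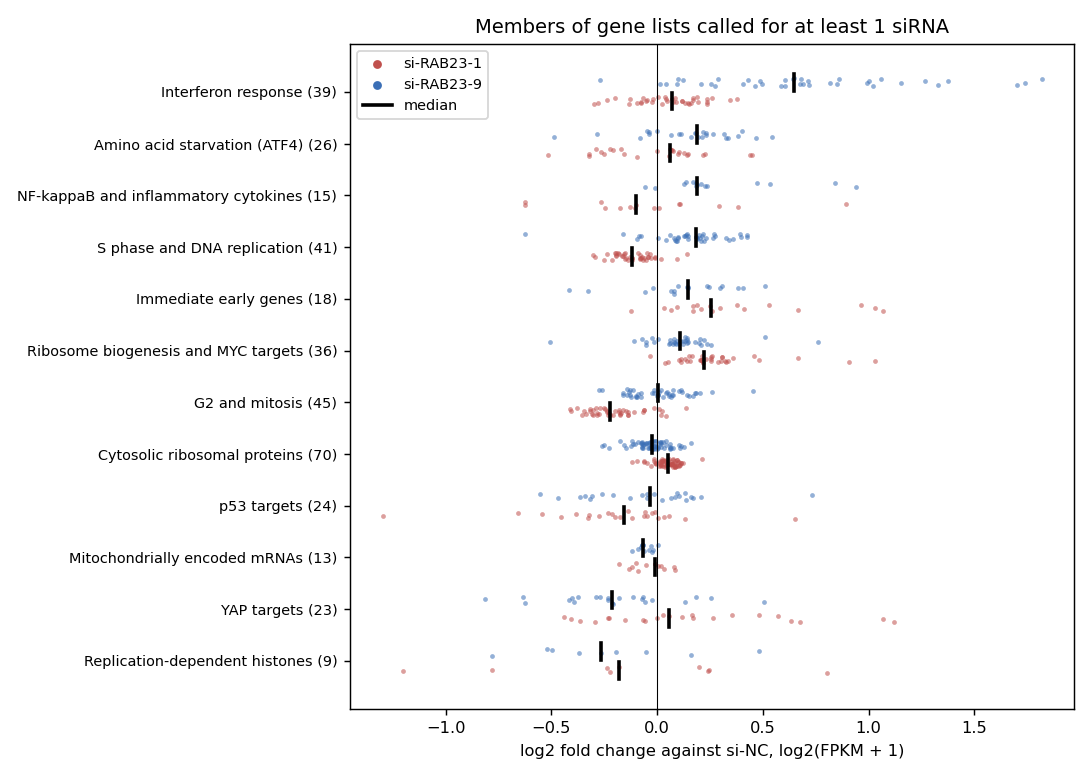
Log2 fold changes of the members of the 12 lists called for at least 1 siRNA, with si-RAB23-1 and si-RAB23-9 minus si-NC on log2(FPKM + 1); points are genes and lines list medians. The interferon list has medians of 0.07 with si-RAB23-1 and 0.64 with si-RAB23-9, and the list of G2 and mitosis has medians of -0.22 and 0.01.

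Some genes tied to the known roles of RAB23 changed, in both directions, and camera, which tests for a shift in 1 direction, called none of their lists. Of all genes tested, 15.39% were called with si-RAB23-1 and 13.25% with si-RAB23-9. The counts of the Hedgehog and cilium lists lie below these shares. Those of the Rab list lie slightly above them, and those of the integrin list well above. The shares of all genes include non-coding genes and genes with few reads. Of the 9467 protein-coding genes scanned for 7-mers, 1045 were higher and 907 lower with si-RAB23-1, and 992 and 713 with si-RAB23-9. Beside these larger shares the Rab counts do not stand out, while those of the integrin list still lie above. Fry, which compares a list with no other genes, called the Rab GTPases with both siRNAs (adjusted p = 0.0408 and 0.0187) and none of the others. Of 15 tested Hedgehog pathway genes, BTRC (-0.35) and KIF7 (-0.29) fell with si-RAB23-1 and PRKACB (-0.31) with si-RAB23-9. The counts of 2 and 1 were the same adjusted over the list alone (camera adjusted p = 0.94 and 0.928). None of these calls held throughout: KIF7 was lost without any 1 of the 6 libraries (limma adjusted p = 0.0672 to 0.142), BTRC without either si-NC library (0.0555 and 0.0708), and PRKACB without any si-NC or si-RAB23-9 library (0.0754 to 0.106). Among 45 genes of other Rab GTPases and a Rab effector, 4 rose and 5 fell with si-RAB23-1, and 7 fell with si-RAB23-9, also when adjusted over the list alone (camera adjusted p = 0.43 and 0.105). RAB8B (-0.70), RAB15 (-0.72) and RAB22A (-0.40) fell with si-RAB23-1, RAB8A (-0.38) with si-RAB23-9, and RAB2B with both (-0.42 and -0.40). RAB8B, RAB22A and RAB2B carry GACATAT, and RAB8A carries AAGTTAA. RAB22A also carries AAGTTAA and TCGGAGA. In the list of the RAB23 exchange factor and cilium trafficking, 1 of 47 rose and 2 fell with si-RAB23-1, and 1 rose and 5 fell with si-RAB23-9. Adjusted over the list alone, 2 fell with si-RAB23-1, and 1 rose and 5 fell with si-RAB23-9 (camera adjusted p = 0.94 and 0.343). KIF3A, the gene of a ciliary kinesin motor, fell with both (-0.46 and -0.34), as did EVI5 (-0.40 and -0.46), which has 2 copies of AAGTTAA. Of 31 integrin and focal adhesion genes, 7 rose and 7 fell with si-RAB23-1, and 4 rose and 10 fell with si-RAB23-9 (10 and 10, and 7 and 13, adjusted over the list alone). Their camera adjusted p values were 0.94 and 0.0855. The GTPase gene RAC1 (0.52 and 0.48) and the integrin gene ITGB8 (0.52 and 0.45) rose with both. ITGB1, which carries GACATAT, fell with si-RAB23-1 (-0.58), and ITGB4 fell with si-RAB23-9 (-0.43). ITGB1, which lacks AAGTTAA, was also called lower with si-RAB23-9 (-0.215 to -0.163 with 1 library left out). Among the Rab, cilium and adhesion genes named, the calls of RAC1 for both siRNAs and of KIF3A, ITGB8 and ITGB1 for si-RAB23-1 held with any 1 library left out. The others were each lost without at least 1 library.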

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

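The results here are those for which the siRNAs differed from each other by a direct test, and all 3 tests of explanations in this part were chosen after the result was seen. Camera called 12 lists between the siRNAs, and their genes are counted here as higher or lower with si-RAB23-9 than with si-RAB23-1 by limma, with the count adjusted over the list alone and the camera adjusted p in brackets. Shifted to higher were interferon response, with 32 of 39 higher (33; 6.75e-18), S phase, with 26 of 41 higher and 1 lower (30 and 1; 3.87e-11), and G2 and mitosis, with 27 of 45 higher (28; 6.2e-10). So were NF-kappaB and inflammatory cytokines, with 10 of 15 higher (12 higher and 1 lower; 0.000114), amino acid starvation, with 10 of 26 higher and 1 lower (13 and 3; 0.00192), and cholesterol biosynthesis, with 7 of 25 higher and 2 lower (7 and 2; 0.0405). Shifted to lower were YAP targets, with 13 of 23 lower (1 higher and 15 lower; 2.77e-06), ribosome biogenesis and MYC targets, with 9 of 36 lower (14; 6.92e-06), and cytosolic ribosomal proteins, with 13 of 70 lower (13; 7.91e-06). So were immediate early genes, with 1 of 18 higher and 7 lower (1 and 10; 0.00361), epithelial junction and keratin, with 5 of 32 higher and 12 lower (6 and 14; 0.00515), and housekeeping reference genes, with 1 of 12 higher and 6 lower (1 and 7; 0.00663). With an estimated correlation the adjusted p of these lists lay between 0.214 and 0.463. The calls of the cytosolic ribosomal protein and housekeeping lists were lost under quantile normalization (adjusted p = 0.498 and 0.408), that of the epithelial list without si-RAB23-1 replicate 2 (0.0815), and that of the cholesterol list without si-RAB23-1 replicate 1 (0.0535) or 2 (0.09), without si-RAB23-9 replicate 1 (0.071) and under 5 further alternatives (0.0518 to 0.306).

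Among single genes, the difference between si-RAB23-9 and si-RAB23-1 on the log2 scale was -1.92 for SPP1, -0.867 for TM4SF1, -0.573 for MARCKS, -0.363 for AREG and -1.51 for CTGF, which si-RAB23-1 had raised. It was 1.69 for AC233266.1, 0.983 for KRT80, 0.828 for TP53INP1, 0.831 for HIST1H2BC and 0.779 for ALPP, which si-RAB23-1 had lowered. The difference was 1.66 for BST2, 1.54 for IFI6, 1.46 for IFITM1, 1.43 for OAS2 and 1.41 for OAS1, and -1.46 for NCEH1, -1.51 for S100A10, -0.97 for MFSD6, -1.08 for RF00019 and -0.831 for AC005392.2. AC233266.1, RF00019 and AC005392.2 rest on fewer than 50 reads per group.

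For the interferon genes, loss of RAB23 transcript alone is argued against as the cause, since it fell to 0.322 and 0.372 times the control while 32 of 39 members differed between the siRNAs. This is the same difference for which the list was flagged, so it is no independent test. RAB23 protein was not measured in these data. RNA from leukocytes is argued against too: apart from CSF1R, which the line expresses, reads of the 15 other markers came to 162 with si-NC, 113 with si-RAB23-1 and 114 with si-RAB23-9 (exact binomial p = 0.941 for more with si-RAB23-9 than with si-NC), while the interferon list, without IFNB1 and IFNL1, gained 54268 reads with si-RAB23-9, though LYZ (3, 5 and 8) and CD74 (27, 22 and 35) had a few more reads there. Sensing of the si-RAB23-9 duplex by the cells stays open and may account for the pattern, since reads of the interferon genes IFNB1 and IFNL1 together came to 22 with si-NC, 12 with si-RAB23-1 and 55 with si-RAB23-9 (exact binomial p = 4.75e-06 against si-NC and 9.77e-09 against si-RAB23-1, for counting error only). These reads do not tell a duplex from another inducer, IFNB1 and IFNL1 belong to the interferon list themselves, and a difference between transfections was not tested.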

How the results depend on the processing

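RAB23 fell under each alternative that tested it (it was not in the set with a mean FPKM of at least 5); with a log2 fold change of at least 1 required, si-RAB23-9 missed it at -0.95. Pseudocounts of 0.1 and 0.5, median-of-ratios scaling, quantile normalization, robust eBayes and the added filter on 10 reads kept the counts of higher and lower genes within 1.5 times. Over the 303 other gene results named, 4837 of 6013 values under alternatives kept their direction and call, 1176 kept only their direction and 0 changed sign. With 1 library left out, 1165 of 1818 kept their call, and 102 of the 303 results kept it whichever library was left out. Leaving out a library leaves 1 library in a group, which is assumed to vary like the others, and fewer degrees of freedom. The counts then ranged from 173 to 954 higher and 165 to 866 lower with si-RAB23-1, from 143 to 1173 and 115 to 902 with si-RAB23-9, from 375 to 1376 and 330 to 1315 for the siRNAs against each other, and from 55 to 347 and 19 to 183 for both. Pearson r ranged from 0.314 to 0.531, and it was 0.355 with a mean FPKM of at least 5. A correlation was taken as unchanged within 10 percent, a limit set after the values were seen since r has no replicate spread. The covariance moved with pseudocounts, filters and voom, from 0.0164 to 0.0733. RAB23 ranged from -1.08 to -1.04 and from -0.978 to -0.921, with limma adjusted p up to 0.0473. Lists called ranged from 6 to 8, 7 to 9 and 11 to 13.

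Without a filter on low values, more genes were tested and the counts were 543 and 506 with si-RAB23-1, 552 and 431 with si-RAB23-9, 771 and 687 between the siRNAs, and 192 and 130 for both, and 10 lists were called for si-RAB23-1. With only the compared groups in the model, which leaves fewer samples, they were 633 and 601 with si-RAB23-1, 1036 and 883 between the siRNAs, and 273 and 167 for both. With si-RAB23-9 they were 1182 and 911, above the main counts of 1085 and 817. The number of samples alone therefore does not account for the lower counts. Without the mean-variance trend 744 were higher with si-RAB23-1, 719 with si-RAB23-9 and 242 with both; the cause was not tested. A required log2 fold change of at least 1 left 24 and 18, 24 and 19, 26 and 34, and 2 and 4 for both. Voom on the recovered reads, chosen after seeing the data, gave 2178 lower with si-RAB23-1, 1872 and 1536 with si-RAB23-9, 2695 higher between the siRNAs, and 663 and 604 for both. With median-of-ratios sizes it gave 1879 and 1915, 1802 and 1605, and 711 and 558 for both, with 10 lists for si-RAB23-1; the cause was not tested. That test also called 2099 of the 2209 genes of si-RAB23-1, 1806 of 1902 of si-RAB23-9, 398 of 420 higher with both and 201 of 218 lower with both, in the same direction.

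Camera with an estimated correlation called 0, 0 and 0 lists, against 6, 9 and 12 with the preset one, and the smallest unadjusted p with si-NC as reference was 0.00492. These settings differ in their degrees of freedom as well as in the correlation. The amino acid starvation list with si-RAB23-9 had an estimated correlation of -0.0095, below the preset 0.01. Its unadjusted camera p still went from 9.04e-05 to 0.0221. Lost calls therefore cannot be put down to correlation between genes alone. With fry, 5 of the lists called by camera lost their call: cytosolic ribosomal proteins with si-RAB23-1 (adjusted p = 0.123), and ribosome biogenesis (0.0747), immediate early genes (0.0605), histones (0.0605) and mitochondrial mRNAs (0.179) with si-RAB23-9. Fry, which tests whether a list's genes move on balance one way and compares with no other genes, called 11, 9 and 23. The cytosolic ribosomal protein list with si-RAB23-1 reversed under quantile normalization (adjusted p = 0.884, lower); the cause was not tested. Scalings moved the median of all genes by under 0.01.

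The labels name no batch behind the replicate numbers. Deviations of same-numbered libraries correlated at -0.0562 (si-NC with si-RAB23-1), -0.0159 (si-NC with si-RAB23-9) and 0.061 (the RAB23 siRNAs) across genes, and at -0.239, 0.0338 and 0.113 over genes with a mean FPKM of at least 5, so they had no common sign. With the replicate block the counts were 856 and 799, 828 and 609, 1299 and 1124, and 299 and 149 for both, and the cholesterol list between the siRNAs lost its call (adjusted p = 0.0621). Count models planned for a table of counts were not run, since the table holds FPKM. Depth limits genes near an FPKM of 1: 974 tested genes had a mean under 10 reads.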

Other observations

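In this part the tests of 2 or more copies of a 7-mer against 1 copy had their outcome written down before they were run, but after the scan, and the other tests of explanations were chosen after the result was seen. Camera did not call the lists below against si-NC, although single members changed. Fry called some of them: with si-RAB23-1 the epithelial list (adjusted p = 0.0204), YAP targets (0.0204), Wnt targets (0.0197), the RNA interference machinery (0.00169) and NRF2 targets (0.00169), and with si-RAB23-9 the mesenchymal list (0.0307), the unfolded protein response (0.0408) and NRF2 targets (0.0197). Of 32 genes of epithelial junctions and keratins, 10 rose and 1 fell with si-RAB23-1 (12 and 3 adjusted over the list alone; camera adjusted p = 0.128), with the desmosomal cadherin gene DSG3 at 0.91, KRT6A at 1.04 and CLDN1 at 0.46, and 3 rose and 3 fell with si-RAB23-9 (4 and 4; camera adjusted p = 0.592), with KRT8 at -0.23. Of 20 mesenchymal genes, 4 rose and 5 fell with si-RAB23-1 (5 and 5 adjusted over the list alone; camera adjusted p = 0.833), and 5 rose and 2 fell with si-RAB23-9 (6 and 2; camera adjusted p = 0.0957). Fibronectin (FN1) rose with both (0.84 and 0.52) and LOXL2 fell with both (-0.30 and -0.40), while S100A4 fell with si-RAB23-1 (-0.73) and rose with si-RAB23-9 (0.50). Of 17 squamous differentiation genes, 3 rose and 3 fell with si-RAB23-1 (4 and 3; camera adjusted p = 0.827), and 4 rose and 2 fell with si-RAB23-9 (8 and 2; camera adjusted p = 0.138), with SCEL lower with both (-0.42 and -0.71). Of 21 NRF2 targets, 10 rose and 3 fell with si-RAB23-1 (10 and 4; camera adjusted p = 0.128), and 4 rose and 3 fell with si-RAB23-9 (6 and 5; camera adjusted p = 0.596). TXNRD1 fell with both (-0.84 and -0.38), and ME1 (0.60 and 0.40) and FTL (0.29 and 0.33) rose with both. Of 14 genes of the RNA interference machinery, 2 rose and 3 fell with each siRNA (2 and 4, and 3 and 3, adjusted over the list alone; camera adjusted p = 0.226 and 0.969). DICER1 fell with both (-0.66 and -0.30) and carries 2 copies of GACATAT, as does AGO4 (-0.43 with si-RAB23-1). Without at least 1 library the calls of DICER1 for both siRNAs, of AGO4, and of FN1 for si-RAB23-9 were each lost. The change of DICER1 with si-RAB23-9 then ranged from -0.376 to -0.227.

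Counts over all genes for the remaining lists are given here for si-RAB23-1 and then si-RAB23-9, each followed by the count adjusted over the list alone and the camera adjusted p. TGF-beta targets: 8 of 25 rose and 5 fell (8 and 8; 0.879), then 7 rose and 5 fell (8 and 6; 0.608). ERK feedback targets: 6 of 24 rose and 6 fell (7 and 7; 0.827), then 3 rose and 5 fell (4 and 8; 0.105). Wnt targets: 1 of 7 rose and 1 fell (1 and 2; 0.27), then 1 rose and 2 fell (2 and 2; 0.969). Apoptosis regulators: 3 of 26 rose and 2 fell (4 and 2; 0.608), then 3 rose and 2 fell (5 and 3; 0.596). The unfolded protein response had 2 of 24 higher and 3 lower (2 and 3; 0.928), then 1 higher and 2 lower (1 and 3; 0.138). Cholesterol biosynthesis had 4 of 25 lower (1 higher and 4 lower; 0.27), then 5 higher and 1 lower (7 and 3; 0.27). Hypoxia and glycolysis had 4 of 31 higher and 4 lower (6 and 4; 0.879), then 2 higher and 8 lower (4 and 8; 0.179). Nuclear oxidative phosphorylation genes had 3 of 42 higher and 1 lower (3 and 1; 0.667), then 3 higher (3; 0.596). Autophagy and lysosome had 4 of 35 higher and 1 lower (4 and 1; 0.53), then 4 and 4 (4 and 7; 0.385). Heat shock genes had 3 of 15 higher (3; 0.0957), then 2 higher and 1 lower (2 and 2; 0.43). Housekeeping genes had 3 of 12 higher (3; 0.105), then 1 higher and 2 lower (2 and 2; 0.43), and the latter included B2M (-0.54), with 3 copies of AAGTTAA. With si-RAB23-1 the interferon list had 5 of 39 higher and 1 lower (5 and 3; 0.348), NF-kappaB targets 2 of 15 higher and 3 lower (2 and 4; 0.343), amino acid starvation genes 4 of 26 higher and 6 lower (8 and 8; 0.94), YAP targets 9 of 23 higher and 4 lower (10 and 7; 0.27), histones 1 of 9 higher and 2 lower (2 and 4; 0.656), and mitochondrial mRNAs 2 of 13 lower (4; 0.179). With si-RAB23-9 the genes of G2 and mitosis had 3 of 45 higher and 1 lower (1 higher; 0.969), p53 targets 1 of 24 higher and 6 lower (2 and 7; 0.254), and cytosolic ribosomal proteins 3 of 70 lower (2; 0.105). The marker lists held 2 tested fibroblast genes, 1 leukocyte, 1 endothelial and 4 columnar ones; FBLN1 (-0.38) and CDH5 (-0.77) fell with si-RAB23-1, and CSF1R (-0.45) and KRT8 with si-RAB23-9.

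Carriers of particular 7-mers in the 3′ UTR were lower as a set with a given siRNA. Of 16292 7-mers, GACATAT led with si-RAB23-1 (705 carriers, effect -0.175, t = -20.9; t = -0.255 with si-RAB23-9) and AAGTTAA with si-RAB23-9 (1563 carriers, effect -0.109, t = -18.4; t = 0.973 with si-RAB23-1), while 100 shuffles gave at most an absolute t of 4.96 and 5.41. These effects are those left after UTR length, the share of G and C and expression had been taken out. Rearranged 7-mers of the same letters had median effects of -0.00368 and -0.0118. The lowest reached -0.0745 (TGACATA) and -0.106 (AGTTAAA), each the leading 7-mer shifted by 1 base. Because the share of G and C had already been removed, medians near 0 cannot serve as a test of base composition. They show only that most other orders of the same letters had smaller effects. Seed-matched targeting by the siRNAs is a hypothesis and may account for part of these changes: genes with 2 or more copies lay lower than those with 1 by a median difference of -0.0566 for AAGTTAA (one-sided permutation p = 2e-04), and by -0.0524 for GACATAT, which missed the threshold (permutation p = 0.111). After that miss, copies followed by A were set against copies followed by another base, with differences of -0.0849 for GACATAT (161 against 485 genes, permutation p = 8e-04) and -0.0574 for AAGTTAA (454 against 727 genes, permutation p = 1e-04, the smallest the resampling can give), but the scan had already ranked ACATATA (-0.0808) and AGTTAAA second, so this comparison adds no support, and the link to the siRNAs stays open because their sequences are not given in the sources used here.

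The 7-mers leading for each siRNA also occur in RAB23 itself. Its scanned transcript is 4837 bases long, and among all 9467 genes scanned 705 hold GACATAT and 1563 hold AAGTTAA in the 3′ UTR. Their presence in RAB23 therefore does not by itself link them to the siRNAs. On GRCh38, GACATAT lies at chromosome 6, 57189788 to 57189794 and 57188043 to 57188049, both in the 3′ UTR of RAB23. AAGTTAA lies in its coding sequence at 57194815 to 57194821, and a further copy spans an exon junction. Carriers of GACATAT were also called lower with si-RAB23-9 more often than other genes (11.4% against 7.22%). These are raw shares, and the effect adjusted for UTR length, base composition and expression did not show it (t = -0.255). Without carriers of GACATAT, AAGTTAA or TCGGAGA, the scanned genes that were lower numbered 582 of 907 with si-RAB23-1 and 344 of 713 with si-RAB23-9. Those higher with both siRNAs numbered 329 of 399 (82.5%), and those lower with both 104 of 187 (55.6%), beside 7277 of all 9467 genes scanned (76.9%). Genes carrying only other 7-mers, such as AGTTAAA or ACATATA, stay in these counts.

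The genes changed alike by both siRNAs were weighed against their shared controls. Independent sampling spread of each si-NC library is argued against as the whole source, since the covariance stayed above 0 when the siRNAs shared no si-NC library (0.00868 with a standard error over chromosomes of 0.00116, and 0.011 with 0.00131), although it fell from 0.0243. These standard errors measure the spread between genes, not between libraries. A deviation common to both si-NC libraries is not excluded, since it would leave the covariance above 0 as well. A seed effect of si-NC that is absent from the other groups may contribute: carriers of TCGGAGA were higher with both siRNAs (effects of 0.105 and 0.116, t = 7.11 and 8.30). The scan of these same data had picked TCGGAGA as the 7-mer leading upward for both siRNAs. Of 399 genes higher with both, 31 carry TCGGAGA in the scanned UTR (7.77%, against 1.91% of the other genes scanned). Direct matches to this 7-mer thus cover few of them. The share cannot exclude a si-NC seed effect as the whole cause. It leaves out overlapping 7-mers such as CGGAGAA, sites outside the scanned UTR and secondary changes. Loss of RAB23 stays open as a hypothesis too, since no group of these libraries separates it from other effects that both siRNAs share.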
